A study of Mus musculus with 4 samples.

How the data were processed

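The series holds 4 libraries from lungs of mice with a tamoxifen-inducible Cre recombinase in the Cdh11 locus and a Cre-dependent YFP reporter in Rosa26: a gene expression and a hashtag library of YFP-positive cells, and the same of YFP-negative cells. Mice received tamoxifen into the peritoneum daily for 5 days and were sacrificed on day 7, per the labels. Libraries were made with the 10x Genomics Chromium 3′ kit, per the labels' protocols. Cell Ranger 7.1.0, bcl2fastq and build GRCm38 are named in the submitters' processing notes; the annotation release and the cell-calling settings are not stated there. The deposited values used here are raw UMI counts per gene and cell barcode, with no normalization, as whole numbers per the file headers, and the same table holds counts of 5 hashtag antibodies. Only the YFP-positive count table was used; for the YFP-negative library only the number of barcodes was counted, and 77 barcode sequences occurred in both. The hashtags are named by number and tied to no animal, so that the library counted as 1 sample.

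The classes of comparison, the gene lists, the markers, the filters and the rule for named genes were fixed before the data were examined. Of 52636 gene IDs, 52403 are in GENCODE M21, from which coordinates on GRCm38 were taken. Of 199 list members, 198 were found, 3 symbols of lists and markers through an older name, and Ccl19 was not used. Fixed after the data were examined were 15 neighbours for the graph, the thresholds for naming clusters and 3 added alternatives: cells with Pi16 or Npnt UMIs in place of the classes, 4 clusters with markers of both fibroblast classes put in the class with the larger share of its markers on (the nearer class; 1 such cluster had equal shares), and another random draw in the thinning. A table of 20 such draws was added when the first change of draw altered the named genes; an earlier draw, made within each class, had then been seen and is kept as that alternative.

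Of 7512 barcodes, 7327 had at least 500 genes, at least 1000 UMIs and under 10% mitochondrial UMIs; 83 fell short of the gene minimum, 98 of the UMI minimum and 134 had too high a mitochondrial share, 185 barcodes in all. The kept barcodes had a median of 9176.5 UMIs (quartiles 6974.75 and 11305), 3090 genes and a mitochondrial share of 2.49%. Hashtags were called with HashSolo from the counts of each antibody, which marked 448 doublets (6.11%) and 12 barcodes without a hashtag; medians per set were 313 to 875 UMIs of the own hashtag and 4 to 6 of the highest other. Scrublet, in scanpy 1.11.5, marked 2 barcodes (0.0273%), so that it did not work here, and doublets of cells with the same hashtag remain. Doublets were removed, and 6878 cells stayed, the barcodes without a hashtag among them only in values over all cells.

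Counts were scaled to 10000 per cell and log-transformed, and 30 principal components of 2000 variable genes, without Cdh11, list genes or markers, were clustered with Leiden at resolution 1 (leidenalg 0.10.2, igraph 0.11.9), which gave 21 clusters. A marker counted as on in a cluster when its log2 of CPM, with 10 added, lay above the midpoint of its range over the clusters; markers under 50 CPM in every cluster, or with a range under 4-fold, were not used. A cluster took a class name with at least 3 markers and 50% of the list on, a lead of 25 percentage points over the next list, and no other class leading its top genes; clusters with a median depth under a share of 0.333 of all cells stayed unnamed. Clusters of 1 name were merged.

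Values per class are CPM of the counts summed over its cells, with exact Poisson intervals; shares have exact Clopper-Pearson intervals, and ratios of counts exact conditional binomial intervals, all at 95% and for counting error only. Log2 ratios of single genes have 0.5 counts added, and a class with 0 counts was set to 3 counts for a bound. In a hashtag set with 0 UMIs of a gene in both groups, the sign of its ratio comes from the added counts alone. For shares of cells with a Cdh11 UMI, and for the split of cells by Cdh11, each cell was thinned to 3000 UMIs without replacement, and cells with fewer were left out. List medians used members with at least 50 UMIs over both classes, or at least 50 thinned UMIs in the split by Cdh11. They were placed among 10000 random lists of the same size matched on mean expression (1000 in the further draws). Lists under the 2.5th or above the 97.5th percentile were taken as outside. In the class comparison, members that are also markers of either class were left out of the median. In the split by Cdh11, only Cdh11 itself was left out. With 1 library per group no test was run and no p-value is given; the same direction in each of 5 hashtag sets describes this library only.

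The named genes are Cdh11 and, in the class comparison, up to 3 members of each list with the largest absolute log2 ratio among those with at least 50 UMIs, an interval that excludes a ratio of 1 and 1 direction in every hashtag set. In the split by Cdh11 they are the 10 highest and 5 lowest genes by log2 ratio with at least 200 thinned UMIs under the same conditions, without Cdh11, mitochondrial and ribosomal protein genes and unnamed gene models. The calls on gene ratios were tested on simulated Poisson counts with 200 changed genes. These counts had no variation between cells or hashtag sets beyond counting error, so the shares below hold for that error only. Clustering, the naming of clusters and the splitting of cells by Cdh11 UMIs were not simulated. In the class comparison, over 12585 genes, 78% of genes changed 1.5-fold and 87% of those changed 2-fold were recovered, and 2.33% of unchanged genes were called; for the split by Cdh11 in adventitial-like cells, over 5219 genes, these were 91%, 99% and 2.29%, and in alveolar-like cells, over 2469 genes, 64%, 92% and 1.41%.

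The alternatives tried were no cell filter, a stricter one (1000 genes, 2000 UMIs), called doublets kept, resolutions 0.5 and 2, list and marker genes allowed among the variable genes, clusters from a random part of each cell's UMIs with values from the rest, thinning to 1500 or 6000 UMIs, the mean of per-cell CPM, other count minimums, hashtags called where the top count was at least 3 times the next, and leaving out each hashtag set. The computations ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and anndata 0.12.19.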

Results

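Single-cell RNA sequencing was carried out on lung fibroblasts of mice in which Cdh11, the gene of cadherin-11, drives a tamoxifen-inducible Cre recombinase. Recombination switches on yellow fluorescent protein (YFP), so that cells with an active Cdh11 locus during the 5 daily tamoxifen injections, and their progeny, carry the label. Mice were sacrificed on day 7 at steady state, and YFP-positive and YFP-negative fibroblasts were sorted. There was 1 gene expression library and 1 hashtag library for each sort, and the number of mice is not stated. The YFP-positive library held 7512 cell barcodes with 501 to 37092 UMIs (unique transcript molecules) each. The 7327 barcodes that passed the filters had a median of 9176.5 UMIs, and 6878 cells were analysed after doublet removal. Antibody hashtags split these cells, all but 12, into 5 sets of 1294 to 1450 cells, with median depths of 8885.5 to 9546 UMIs. The hashtags are known only by number, so that the library counted as 1 sample and no difference here has a replicate check. Values are given with the number of hashtag sets that share their direction, and the intervals, at 95%, cover counting error only.

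The sort itself was the first comparison of the series, YFP-positive against YFP-negative cells. The YFP-negative library held 39229 cell barcodes against 7512 in the YFP-positive one. These numbers depend on how many cells were loaded, so they give no share of labelled fibroblasts. Expression in the YFP-negative cells was not analysed here, and no gene in the count table stands for YFP or the Cre recombinase (0 of 52636). Cdh11 transcript was found in 84.9% of the YFP-positive barcodes.

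The next comparison asked which lung cells carried the Cdh11 label. Most named cells were fibroblasts of known positions in the lung: adventitial fibroblast-like cells, which lie around vessels and airways, made up 39.1% of the 6878 cells, and alveolar fibroblast-like cells, which lie in the gas-exchange walls, 15.4%. Mesothelial-like cells, of the kind that lines the lung surface, made up 4.62% and chondrocyte-like cells, of the kind found in airway cartilage, 1.08%. A further 35.3% of the cells fell in 5 clusters that held markers of both fibroblast classes and were left without a class name, since neither class led by enough. Markers of the other class were not absent from the named clusters. Each of the 7 adventitial-like clusters also had 3 of 6 alveolar markers on, and each of the 2 alveolar-like clusters 2 of 9 adventitial ones. Smooth muscle-led, endothelial-led and leukocyte-like clusters held only 17, 16 and 8 cells. The cells had been sorted as fibroblasts, and no YFP-negative expression was analysed. These shares and counts may thus reflect the sort and the make-up of the tissue, and do not show how often each cell type was labelled.

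The adventitial-like class joined 7 clusters with 2686 cells (39.1%, exact 95% interval 37.9 to 40.2%). It had Pi16, a marker of adventitial fibroblasts, at 1403 CPM (UMI counts summed over the class and scaled to a common total) against 118 in the alveolar-like class, and Cd248, an endosialin gene of perivascular stroma, at 305 against 44.5. The alveolar-like class joined 2 clusters with 1057 cells (15.4%, 14.5 to 16.2%), and had Npnt, which encodes the matrix protein nephronectin, at 1180 CPM against 52.4 and Inmt at 6798 against 2764. The 318 mesothelial-like cells (4.14 to 5.15%) had 8 of 8 mesothelial markers on, and the 74 chondrocyte-like cells (0.846 to 1.35%) had 4 chondrocyte markers on. Shares differed between the hashtag sets: adventitial-like cells made up 35.2 to 43.1%, alveolar-like cells 10.6 to 20.5%, mesothelial-like cells 1.52 to 7.70% and chondrocyte-like cells 0.155 to 2.07%. The rank of the named fibroblast classes was the same in 5 of 5 sets.

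The 5 clusters with markers of both fibroblast classes, named here by a leading gene chosen after the values were seen, differed from each other. The Cxcl14-led cluster of 760 cells had Npnt at 402 CPM, Pi16 at 436 and Cxcl14, a chemokine of resting stroma, at 1567. The Angptl7-led cluster of 665 cells had Hhip, which encodes a hedgehog-binding protein and marks peribronchial fibroblasts, at 714, and Notum and Wif1, secreted Wnt antagonists, at 242 and 239, although Wif1 also stood at 212 in the Pappa2-led cluster. The Ntrk2-led cluster of 505 cells had Col15a1 at 524, the Foxd1-led cluster of 315 cells had Pi16 at 1200, and the Pappa2-led cluster of 184 cells had Aspn, an asporin gene, at 383. These genes were not particular to 1 cluster. Pi16 stood at 947 and Col15a1 at 373 in the Angptl7-led cluster, and Hhip at 453 in the Cxcl14-led cluster. Aspn was at 302 in the Foxd1-led cluster and at 1112 in chondrocyte-like cells. A further cluster of 251 cells was left unnamed for its low median of 2690 UMIs. The shares rest on where the clusters are split: with clustering resolution 0.5 the alveolar-like share was 4.97%, and with 4 of the 5 clusters that held both kinds of marker put in the nearer class it was 36.1%.

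**Figure D1:**
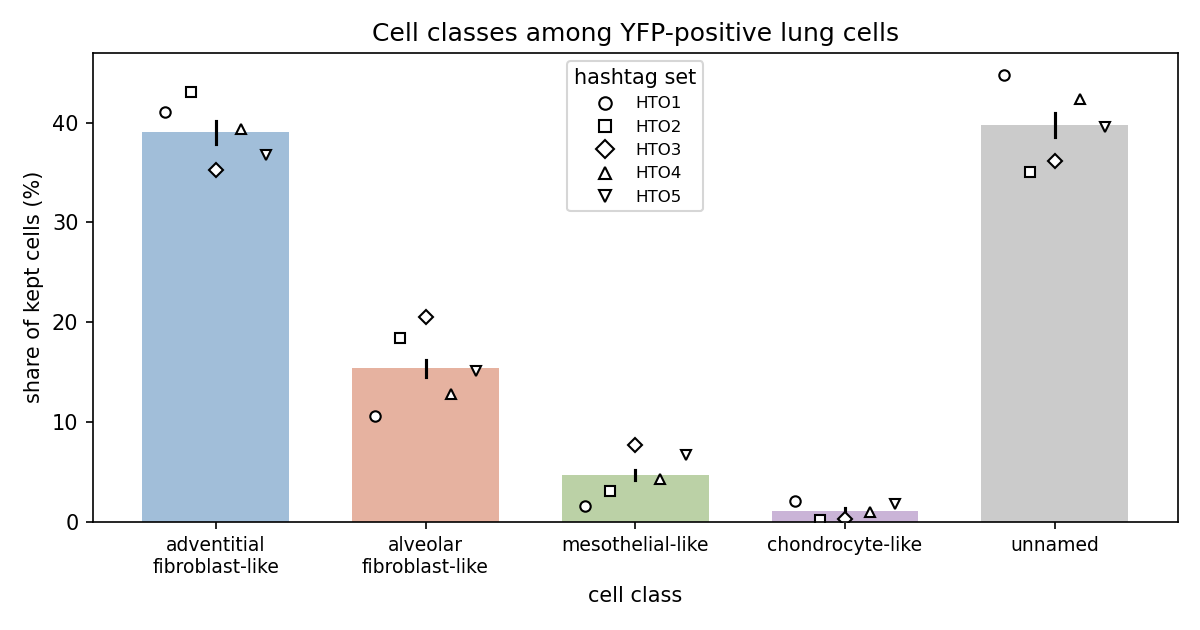
Share of the 6878 YFP-positive cells in each class (bars, percent of cells, with exact 95% intervals as black lines) and in each of 5 hashtag sets (symbols). Adventitial-like cells lie between 35.2 and 43.1% and alveolar-like cells between 10.6 and 20.5% over the sets; the leukocyte-like class of 8 cells is not drawn.

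Cdh11 itself was then compared between the classes, since its locus drives the label. Fibroblast-like, mesothelial-like and chondrocyte-like cells all carried the transcript, but at different levels. It was highest in chondrocyte-like cells at 790 CPM, followed by alveolar-like cells at 587, adventitial-like cells at 322 and mesothelial-like cells at 287. Adventitial-like cells, the most numerous named class, thus had 1.82-fold less Cdh11 than alveolar-like cells. All these cells had been sorted on a label driven by the Cdh11 locus. The levels thus hold for labelled cells and not for each cell type as a whole. The order of adventitial-like against mesothelial-like cells was not the same in every hashtag set. Adventitial-like cells stood lower in HTO1 (286 against 312 CPM) and HTO4 (310 against 318), and higher in HTO2, HTO3 and HTO5. Cells left unnamed had 520 CPM.

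The log2 ratio of Cdh11 (ENSMUSG00000031673, chromosome 8, 102632095 to 102785642, GRCm38) in adventitial-like over alveolar-like cells was -0.87 (95% interval -0.92 to -0.81), from 8244 and 5171 UMIs. It was negative in 5 of 5 hashtag sets, from -1.01 to -0.73. With every cell thinned to 3000 UMIs, 53.2% (51.3 to 55.1%) of 2631 adventitial-like cells and 77.1% (74.4 to 79.6%) of 1036 alveolar-like cells had a Cdh11 UMI. The share was 53.2% of 316 mesothelial-like cells and 79.5% of 73 chondrocyte-like cells. As background, 0 of 15 cells in the smooth muscle-led cluster, 1 of 13 in the endothelial-led cluster and 1 of 6 leukocyte-like cells had one at the same depth, for a joint 5.88% (0.720 to 19.7%). Before thinning, the median depth was 6215.5 UMIs in those cells, 9413.5 in adventitial-like and 7772 in alveolar-like cells. The upper 95% limit of the smooth muscle-led share of 0 is 21.8%.

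Within the adventitial-like class, Cdh11 differed more between clusters than between the classes. The Adra1b-led cluster of 749 cells had 432 CPM (418 to 447), while the Esm1-led cluster, with Tgfbi, had 211, the Ccl8-led cluster 218 and the Ifi207-led cluster 123 (104 to 146). The alveolar-like clusters had 603 (584 to 623) and 546 (518 to 576). Of the clusters with markers of both classes, the Cxcl14-led cluster had 684 (665 to 704), the Angptl7-led cluster 519, the Pappa2-led cluster 474, the Foxd1-led cluster 470 and the Ntrk2-led cluster 387. Grouping cells by marker UMIs, a grouping added after the data were seen, gave 371 CPM in 3171 cells with Pi16 and no Npnt and 596 in 1276 cells with Npnt and no Pi16. The 651 cells with both had 577 (544 to 612), near the level with Npnt only, and the 1158 with neither had 406. Mesothelial-like and leukocyte-like cells and clusters under 50 cells were left out.

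**Figure D2:**
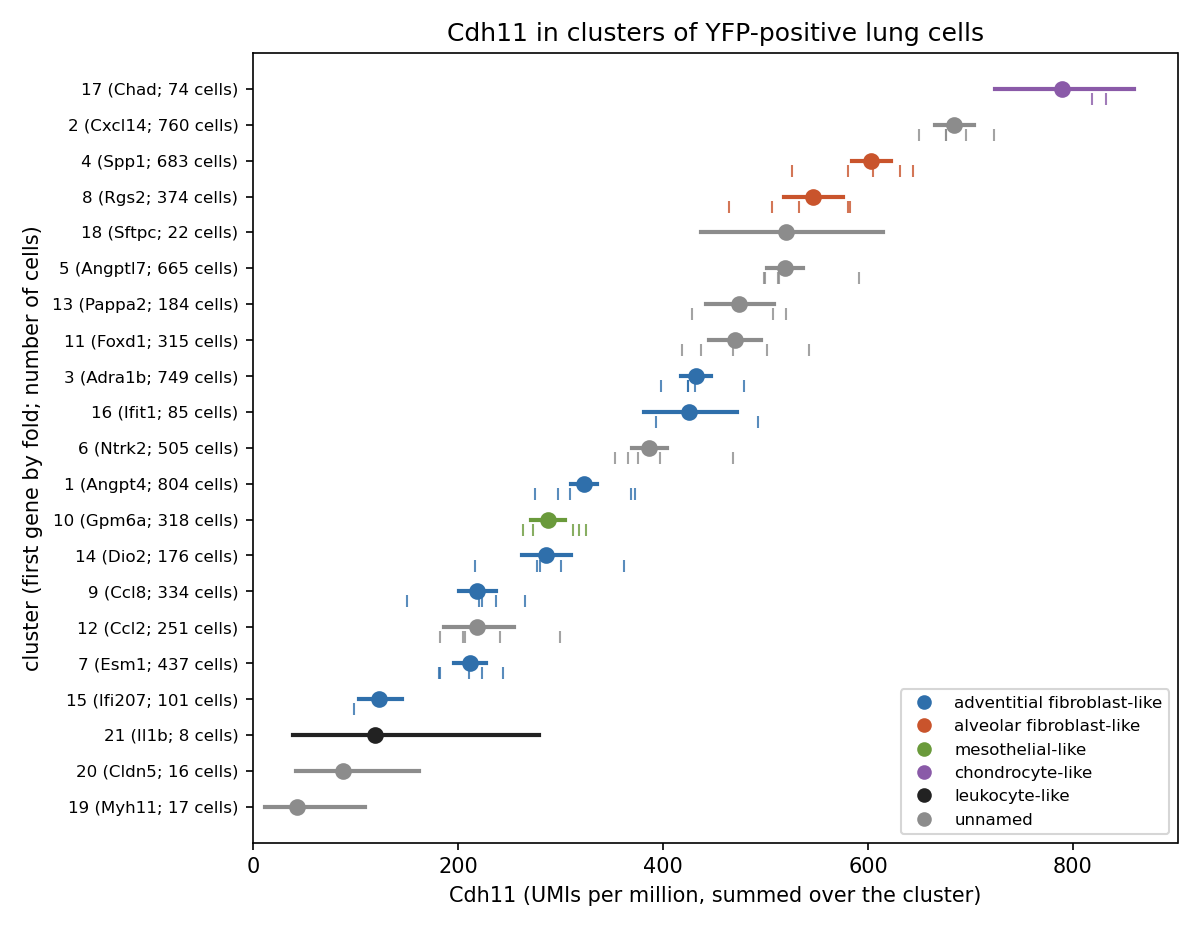
Cdh11 in each of 21 clusters, in CPM summed over the cluster (horizontal axis); dots are clusters, coloured by class, lines are exact 95% intervals, and small ticks are hashtag sets with 20 or more cells. The chondrocyte-like cluster stands highest at 790 and the smooth muscle-led cluster lowest at 42.7.

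Fixed gene lists were compared between the adventitial-like and alveolar-like classes to describe the main labelled fibroblasts. In adventitial-like cells, 10 of 14 proteases and inhibitors and 9 of 10 complement genes were higher in every hashtag set. The medians of the chemokine, Wnt and basement membrane lists also lay above the random lists, but with 5 of 12, 5 of 10 and 8 of 15 members higher, and the Wnt and basement membrane medians turned negative under other settings. Decorin, a collagen-binding proteoglycan, reached 12256 CPM in them against 1484 in alveolar-like cells, and Il33, an alarmin cytokine, 112 against 4.43. In alveolar-like cells 7 of the 15 activated fibroblast and TGF-beta response genes were higher in every set and 3 were lower, and this list's median also turned under another setting. Cxcl14 (899 against 123) and the growth factor genes Hgf and Fgf7 were higher in them as well. The enzymes that make retinoic acid were divided: Aldh1a1 was higher in alveolar-like cells, and Aldh1a2 and Aldh1a3 in adventitial-like cells.

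The median log2 ratio of 5 of the 14 lists lay above that of the random lists matched on expression, and that of 3 lay below. The ratios are adventitial-like over alveolar-like; the median over all 12585 genes with at least 50 UMIs was -0.061. The proteases and inhibitors had a median of 0.89, above all 10000 random lists, with 10 of 14 members higher in every hashtag set and 0 lower. Mmp23, a membrane-bound metalloproteinase gene, was higher by a log2 ratio of 2.21, Adamts5, an aggrecan-cleaving protease gene, by 1.88, and Htra1, a secreted serine protease gene, by 1.81. The complement list had a median of 0.75, above all random lists, with 9 of 10 members higher in every set. Among them were C3, the central component (1.06, interval 1.03 to 1.09), and Cfb, of the alternative pathway (1.91), while C7, of the terminal pathway, was lower (-1.02).

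The Wnt list had a median of 0.73 (99.99th percentile), with 5 of 10 members higher in every set and 1 lower. Sfrp4, a secreted Wnt antagonist, was higher by 4.29 and Rspo1, which amplifies Wnt signals, by 2.04. Wnt2, a ligand that also served as a marker of the alveolar class and so was left out of the median, was lower (-1.30). This median turned negative with called doublets kept (-0.15) and with the nearer class (-0.14). The chemokine and cytokine list had a median of 0.44 (99.88th percentile), with 5 of 12 members higher in every set and 2 lower; without hashtag set HTO1 the median was 0.13. Il33 was higher by 4.64, with UMIs in 1099 of 2686 adventitial-like and 24 of 1057 alveolar-like cells, and Cxcl12, a ligand for leukocyte homing, by 1.37. Cxcl14 was lower (-2.87). The basement membrane list had a median of 0.30 (99.66th percentile), with 8 of 15 members higher in every set and 4 lower. Col4a3 (2.48) and Col4a4 (2.97), chains of collagen IV, and Nid2, a nidogen gene (1.80), were among the higher ones; the median was -0.076 with called doublets kept.

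The activated fibroblast and TGF-beta response list had a median of -0.89, below all random lists, with 7 of 15 members lower in every set and 3 higher. Tnc, the tenascin-C gene, had 1 UMI in adventitial-like and 92 in alveolar-like cells (-7.48, interval -13.38 to -5.55), but its ratio was -0.88 with list and marker genes allowed in the clustering. Tgfbi, a TGF-beta-induced matrix gene (3.74), and Fap, a fibroblast activation protease gene (3.39), went the other way. Without hashtag set HTO5 this median was -0.32, and with those genes allowed it was 0.10. The cell cycle list had a median of -2.21, below all random lists, from few cells. With 0.5 counts added, 6 of 9 members counted as lower in every set and 0 as higher. A gene with 0 UMIs in both classes of a set counts as lower, since the adventitial-like class has more UMIs in total. For such genes these numbers do not show that the sets agree. Mki67, a proliferation marker, had UMIs in 10 of 1057 alveolar-like cells (0.946%, 0.455 to 1.73%) and 0 of 2686 adventitial-like cells (upper limit 0.137%). Its CPM was 76.5-fold lower when 3 counts over the class stand for 0. That figure takes the UMIs of those 10 cells as independent and is no firm bound. Its 79 UMIs were uneven, with 3 cells of HTO5 giving 27.8 CPM in that set against 0.910 to 9.30 in the other sets, and the log2 ratio of -8.85 was -1.01 with called doublets kept. Top2a (-5.53), from 3 and 55 UMIs, and Cenpf (-3.86), from 8 and 42, were also lower, and each changed direction under 1 other clustering. In HTO3, Top2a had 0 UMIs in both classes, so that this set gave it no direction of its own. Without hashtag set HTO5 this median was -0.73, and without HTO4 it was -1.09.

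Dissociation stress genes, a sign of handling, had a median of -0.22 (1.05th percentile), with 1 of 15 members higher in every set and 5 lower. Btg2, an antiproliferative early gene, was lower (-1.04), as was Ier3 (-0.62), and the heat-shock gene Hspa1b was higher (0.80). The median was 0.05 with the nearer class. Median depths also differed, at 9413.5 UMIs in adventitial-like and 7772 in alveolar-like cells.

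The remaining 6 lists lay within the random lists and held members that went both ways. Fibrillar collagens and small proteoglycans had a median of 0.088 (53.11th percentile), with 7 of 16 members higher and 4 lower in every set. Dcn was higher by 3.05, Lum, the lumican gene, by 3.73 and Podn, the podocan gene, by 1.90. Elastic fibre genes had a median of -0.059 (13.82nd percentile), with 6 of 16 members higher and 7 lower in every set. Fbln1 (1.38) and Fbln2 (2.52), fibulin genes, were higher, although Fbln2 was at 0.028 with called doublets kept, and Ltbp2, a latent TGF-beta-binding protein gene, was lower (-3.20); this median was 0.15 with clustering resolution 0.5. BMP and TGF-beta family modulators had a median of 0.092 (80.52nd percentile) and a mean of -0.039, with 3 of 11 members higher and 3 lower in every set. Bmp3 (-2.22) and Bmp5 (-1.53) were lower and Fst, the gene of the activin-binding protein follistatin, was higher (1.46). In the lipid and retinoid list (median 0.10, 82.25th percentile), 5 of 12 members were higher and 4 lower in every set. Aldh1a2 was higher by 4.41 and Aldh1a3 by 3.42, and Aldh1a1 was lower (-2.25). In the growth factor list (median 0.074, 85.93rd percentile), 6 of 13 members were higher and 6 lower in every set. Hgf (-1.58) and Fgf7 (-1.07), which act on epithelium, were lower, and Met, the receptor of Hgf, was higher (2.22). The growth factor, BMP and lipid medians also turned negative under other settings, to -0.10, -0.18 and -0.023 at the lowest. Cadherins and catenins, the list with Cdh11 itself, had a median of -0.32 (4.96th percentile), with 4 of 7 members lower and 2 higher in every set. Jup, the plakoglobin gene, was lower (-0.82). Cdh4, the R-cadherin gene, was higher (1.42, interval 0.76 to 2.22), but its ratio was -3.01 with called doublets kept and -1.76 with the nearer class.

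These 42 named genes, 25 higher and 17 lower, kept 1 direction in 5 of 5 hashtag sets by the rule that chose them. That rule used ratios with 0.5 counts added, and sets with 0 UMIs in both classes were not left out. For Top2a the direction in HTO3 came from the added counts alone. Under the other settings tried, the ratio nearest to 0 was -0.063 for Jup, -0.13 for C7, -0.38 for Wnt2, -0.38 for Ier3, 0.54 for Hspa1b, -0.54 for Btg2, 0.63 for Htra1 and -0.70 for Fgf7. It was 0.76 for Col4a3, 0.79 for Fbln1, 0.91 for C3, 0.94 for Mmp23, -0.96 for Hgf, -1.09 for Ltbp2, -1.49 for Bmp3, 1.91 for Lum, 2.07 for Col4a4, 2.34 for Dcn, 2.77 for Fap, 3.47 for Il33, 3.66 for Sfrp4 and 3.69 for Aldh1a2. Among lung genes that fibroblasts should lack, Scgb1a1, of airway club cells, was found in 148 of 2631 thinned adventitial-like (5.63%) and 29 of 1036 alveolar-like cells (2.80%). Sftpc, of alveolar epithelium, was found in 3.12% and 2.90%, and Msln, of mesothelium, in 1.06% and 1.16%.

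**Figure D3:**
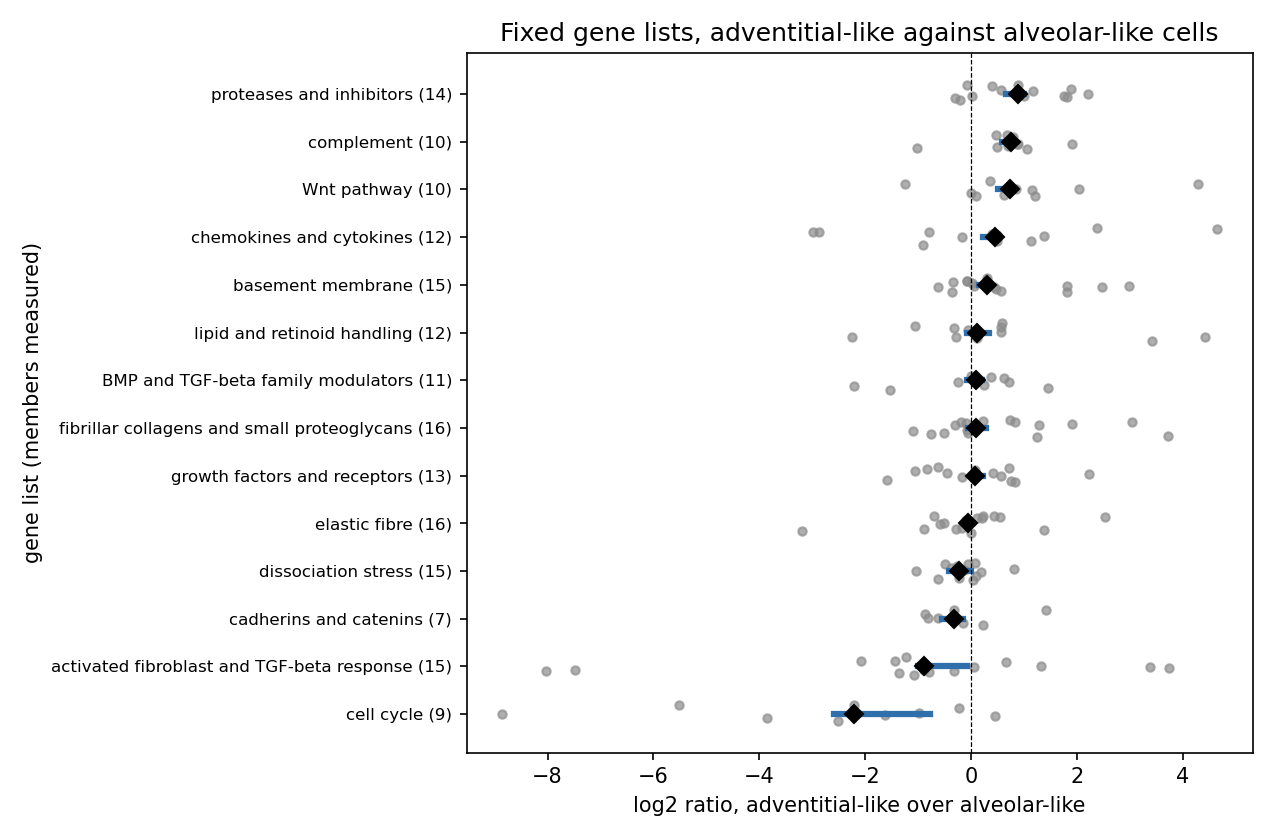
Log2 ratio of adventitial-like over alveolar-like cells for the 14 fixed gene lists; grey dots are measured members, black diamonds list medians, and blue lines the range of the median over 5 hashtag sets. Medians run from 0.89 for proteases and inhibitors to -2.21 for the cell cycle list, whose members had few UMIs.

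The last comparison asked which genes went with Cdh11 transcript inside the sort, in cells thinned to 3000 UMIs. Among adventitial-like cells, the 1400 with a Cdh11 UMI were set against the 1231 without one. Itga8, an integrin chain of mesenchymal cells, was higher by a log2 ratio of 1.29, Fmod, the gene of the collagen-binding proteoglycan fibromodulin, by 1.14 and Bmp3 was 1.99-fold higher. Ebf2, a transcription factor gene, was lower (-1.04), as were Ccl8, a monocyte chemokine gene (-0.86), and Il33 (-0.76). The markers of the adventitial class were themselves lower with Cdh11 (8 of 8, median -0.13), and 5 of 6 alveolar markers were higher (median 0.19). So were 3 of 3 peribronchial or myofibroblast markers (median 0.20) and 2 of 3 smooth muscle markers (0.17).

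In these adventitial-like cells, the other genes named as higher were Macf1, a cytoskeletal crosslinker gene (0.93, interval 0.83 to 1.03), Thbs1, the thrombospondin-1 gene (0.89), Nrp2, a neuropilin gene (0.86), Cxcl14 (0.85), Crispld1 (0.83), Nt5dc2 (0.80) and Limch1 (0.80). Cyp1b1, a cytochrome P450 gene, was also lower (-0.85). Of the fixed lists, fibrillar collagens and small proteoglycans (median 0.16, above all random lists), BMP and TGF-beta family modulators (0.31, 99.99th percentile), basement membrane (0.15, 99.70th), elastic fibre (0.081, 98.75th) and growth factor genes (0.12, 98.14th) lay above the random lists, and chemokines and cytokines (-0.15, 0.51st) below. The fibrillar list had 7 of 16 members higher and 2 lower in every set, the BMP list 3 of 11 and 1, the basement membrane list 5 of 15 and 0 and the growth factor list 2 of 12 and 1. The elastic fibre list had more members lower (4 of 15) than higher (2), and the chemokine list 1 of 10 each way. The BMP median was positive in only 2 of 5 hashtag sets, the elastic fibre median in 3, and the chemokine median negative in only 2. The activated fibroblast median (0.044) and its mean (-0.018) differed in sign. Without HTO1, and likewise without HTO4, 3 lists in place of 6 lay outside, and with called doublets kept the BMP median was -0.0164 and the chemokine median 0.0129.

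The draw of 3000 UMIs decides which cells have a Cdh11 UMI. Over 20 further draws, made after the first had been seen, a median of 7 of the 15 genes were named again, led by Fmod and Bmp3 in 19 draws, Itga8 in 13 and Macf1 and Ebf2 in 12 each. These 5 genes kept their direction in all 20 draws, and so did Thbs1, Nrp2, Cxcl14, Crispld1, Nt5dc2, Limch1, Ccl8, Cyp1b1 and Il33. Thbs1 was named in 0 of 20 draws, with ratios of 0.22 to 0.68 (median 0.51), all below the 0.89 of the first draw, and Crispld1 in 3, from 0.089 to 0.98. The elastic fibre list lay above the random lists in 17 of 20 draws, the fibrillar and growth factor lists in 15 each and the BMP list in 12; the basement membrane list did so in 7, and the chemokine list lay below in 9. The first medians of the BMP, fibrillar and basement membrane lists exceeded those of all 20 draws, which reached 0.26, 0.15 and 0.13, with middle values of 0.13, 0.074 and 0.10. Ebf2, Ccl8 and Cyp1b1 were also leading genes of the Ifi207-led and Ccl8-led clusters, where Cdh11 stood at 123 and 218 CPM. Fmod and Bmp3 were in turn highest, among the adventitial-like clusters, in the Adra1b-led cluster with 432 CPM of Cdh11: Fmod stood at 114.5 there against 0.881 to 68.0 in the others, and Bmp3 at 203 against 11.1 to 70.6.

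Among alveolar-like cells, the 799 with a Cdh11 UMI were set against the 237 without one. Wnt4, a Wnt ligand gene, was higher by 0.98 (0.44 to 1.62) with Cdh11, and Adm, the adrenomedullin gene, by 0.77. Gem, a small GTPase gene, was lower (-1.09, -1.47 to -0.70), and so was S1pr3, a sphingosine 1-phosphate receptor gene (-0.79). Alveolar markers were higher in 7 of 8 cases (median 0.25), adventitial markers in 3 of 7 (median -0.039) and peribronchial or myofibroblast markers in 0 of 3 (median -0.21). The complement list lay above the random lists (0.13, 97.81st percentile) and the activated fibroblast list below (-0.24, 0.66th percentile), although the mean of the latter was 0.61. Complement had 3 of 9 members higher and 1 lower in every set, and a median above 0 in 4 of 5 sets. The activated fibroblast list had 0 of 9 lower and 1 higher, and a median below 0 in only 3 of 5 sets, with 0.24 in HTO4 and 0.23 in HTO5. With another draw the medians turned to -0.028 for complement and 0.16 for the activated fibroblast list.

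The other genes named in alveolar-like cells were Eif4ebp2 (0.69), Islr (0.67), Ccdc12 (0.62), Lamb2 (0.61), Gpx7 (0.61), Crtc3 (0.60), Nxf1 (0.60) and Wwc2 (0.59) as higher, and Nudt4 (-0.73), Ier5 (-0.68) and Ggnbp2 (-0.67) as lower. These names depend on the draw: over 20 further draws a median of 1 of the 15 genes, and at most 2, were named again, Wnt4 in 7 draws and Gem in 4. The first values of Eif4ebp2, Islr, Ccdc12, Gpx7, Nxf1, Gem, Ier5 and Ggnbp2 lay farther from 0 than in any of these draws. Wnt4 kept its direction in 20 of 20 draws (0.30 to 1.08) and Gem in 19, but Wnt4 was at -0.42 with clustering resolution 0.5 and -0.0615 with called doublets kept. The complement list lay above the random lists in 14 of 20 draws, the elastic fibre list in 15 and the growth factor list in 12, while the activated fibroblast list lay below in only 3. Without HTO2, and likewise without HTO3, 1 list in place of 2 lay outside, and without HTO4, 4 did.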

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

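The tests of cluster naming, free Cdh11 RNA, airway amounts and both tests of the cluster with few UMIs were chosen only after the result was seen; those of UMI depth and miscalled hashtags were written before. Of 141 values examined over the 5 hashtag sets, 12 had 1 set far from the other 4, where chance gives about 1 in 20, or 7.05.

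The Ifi207-led cluster made up 2.48% of HTO1 cells against 0.972 to 1.34% elsewhere. In adventitial-like over alveolar-like cells, the BMP list median was -0.0701 in HTO2 (0.12 to 0.20 in the others), the log2 ratio of Tnc was -3.81 in HTO2 (-6.95 to -6.08) and that of Cxcl14 -2.14 in HTO2 (-3.21 to -3.01). In the split of adventitial-like cells by Cdh11, the BMP list median was 0.42 in HTO1 (-0.048 to 0.066), the ratio of Macf1 0.59 in HTO5 (0.94 to 1.06) and that of Nt5dc2 1.34 in HTO1 (0.55 to 0.71). In the split of alveolar-like cells, the protease list median was -0.34 in HTO1 (-0.065 to 0.042), and the ratios were 2.57 for Wnt4 in HTO5 (0.31 to 0.81), 0.89 for Islr in HTO3 (0.53 to 0.62), 1.60 for Wwc2 in HTO2 (0.29 to 0.52) and -0.27 for Ier5 in HTO4 (-0.84 to -0.69).

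Cdh11 was lower in adventitial-like than in alveolar-like cells. Among cells with 6000 to 10000 UMIs, 1185 adventitial-like and 523 alveolar-like, the log2 ratio was -1.01 (-1.09 to -0.93), which argues against UMI depth. Cells with Pi16 and no Npnt UMI against cells with Npnt and no Pi16 UMI gave -0.68 (-0.76 to -0.61), which argues against the way clusters were named as the whole source. Both genes were among the markers that named the clusters, so the choice of markers is not covered. Of 34 smooth muscle-led, endothelial-led and leukocyte-like cells, 5.88% (0.720 to 19.7%) had a Cdh11 UMI, below the gap of 23.9 percentage points between the classes. The smooth muscle-led cells were not part of the background fixed beforehand. The upper limits of the endothelial-led and leukocyte-like shares alone, 36.0% and 64.1%, exceeded the gap. Free Cdh11 RNA as the source therefore stays open. No biological explanation was tested, since the design gives no group for one.

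Chondrocyte-like cells and cells of the Pappa2-led cluster, where Myoc is also a leading gene, were uneven between the hashtag sets. With hashtags called by the ratio of counts, the highest share of these 262 cells was 6.59% in HTO1. It was 8.57 times the lowest, 0.736% in HTO2 (interval 4.67 to 19.3), which argues against the way hashtags were called as the source. The interval does not allow for the choice of the highest and lowest of 5 sets. Both ways of calling used the same antibody counts, so errors in those counts are not covered. The sets stood at the same rank by both shares (5 of 5), but the clusters were joined because both were seen to be uneven. The lowest ranks rest on 2 and 4 chondrocyte-like cells, and 0 of the 4 steps between neighbouring ranks of the chondrocyte-like share exceeded counting error. The steps of the Pappa2-led share were not examined in this way. That share was 0.541% in HTO2, 0.823% in HTO3, 2.41% in HTO4, 4.46% in HTO5 and 4.76% in HTO1. With the chondrocyte-like ranks uncertain, different amounts of cartilage-bearing airway in the tissue of each set stay open. The labels do not say how the lungs were dissected, and no biological explanation was tested.

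A cluster of 251 cells had a median of only 2690 UMIs. Adventitial markers stood 1.37 higher than alveolar markers in median log2 ratio to the whole library, but the 9 adventitial markers ranged from -5.27 to 1.49 and the 8 alveolar ones from -2.72 to 0.51, so free RNA in droplets without a cell stays open. The median mitochondrial share was 1.27% (quartiles 0.848 and 1.82%), against a lower quartile of 2.03% in all kept cells. This argues against damaged cells that lost cytoplasmic RNA but kept their mitochondria. Damage with loss of mitochondria would not raise the share, and barcodes at 10% or more had been removed beforehand. Damage of other kinds therefore stays open. Other sources of a low count, such as small cells, and any biological explanation were not tested.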

How the results depend on the processing

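The comparison of Pi16-only with Npnt-only cells, the nearer class and another random draw were added only after seeing the data. The lower Cdh11 in adventitial-like cells (-0.87) kept its direction under every alternative tried; the log2 ratio was -0.80 with no cell filter, -0.76 with the stricter filter, -1.11 at resolution 2, -0.76 with list and marker genes allowed, -0.93 as the mean of per-cell CPM, -0.68 for Pi16-only over Npnt-only cells, -0.80 with the nearer class and -0.90 to -0.83 without 1 hashtag set. The shares moved more. The adventitial-like share (39.1%) was 47.3% with no cell filter, 46.6% with the stricter filter, 37.4% with doublets kept, 34.3% at resolution 2, 45.2% with list and marker genes allowed, 27.3% with clusters from a part of the UMIs, 36.8% with hashtags by ratio, 51.0% with the nearer class and 38.1 to 40.0% without 1 set. The alveolar-like share (15.4%) was 16.3% with the stricter filter, 22.2% with doublets kept, 4.97% at resolution 0.5, 10.96% at resolution 2, 13.6% with list and marker genes allowed, 12.3% with clusters from a part of the UMIs, 12.9% with hashtags by ratio, 36.1% with the nearer class and 14.1 to 16.6% without 1 set. Lists above the random lists numbered 4 to 6 throughout, those below 1 in place of 3 at resolutions 0.5 and 2 and with list and marker genes allowed. The lists outside in the split by Cdh11 were 3 to 6 without 1 set in adventitial-like cells (6 over all); in alveolar-like cells (2 over all) they were 1 with no cell filter, 5 at resolution 2, with list and marker genes allowed and at 6000 UMIs, 0 with another draw, 1 with the nearer class and 1 to 4 without 1 set.

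List medians that reversed are given where they passed 1 SD over the sets or lay outside the random lists. In the class comparison these were basement membrane (-0.0757) and Wnt (-0.15) with doublets kept, elastic fibre at resolution 0.5 (0.15) and with clusters from a part of the UMIs (0.0447), activated fibroblast with list and marker genes allowed (0.10), and Wnt (-0.14) and dissociation stress (0.0497) with the nearer class; the smaller medians of BMP (to -0.18), growth factor (to -0.10) and lipid genes (to -0.023) changed sign as well. Genes that reversed were Cdh4 with doublets kept (-3.01) and with the nearer class (-1.76), Cenpf at resolution 0.5 (0.0210) and Top2a with list and marker genes allowed (1.30). In the split of alveolar-like cells, Eif4ebp2 (-0.0828), Islr (-0.12), Ccdc12 (-0.0702) and Gpx7 (-0.0827) reversed with no cell filter, Eif4ebp2 (-0.29) with the stricter filter, Wnt4 (-0.0615), Islr (-0.40), Ccdc12 (-0.00429), Ier5 (0.11) and Ggnbp2 (0.15) with doublets kept, Wnt4 (-0.42) and Lamb2 (-0.0361) at resolution 0.5, Islr (-0.0387), Nxf1 (-0.00322) and Ggnbp2 (0.0271) at 1500 UMIs, Islr (-0.0762) at 6000 UMIs, and Eif4ebp2 (-0.25) and Nxf1 (-0.0495) with another draw. The activated fibroblast list median there reversed with doublets kept (0.0603) and with another draw (0.16), and the complement median with another draw (-0.0284). The Wnt (to -0.15) and elastic fibre medians (to -0.018) of these cells, within the random lists, changed sign as well. The fibrillar list median there reversed at resolution 2 (0.12), with list and marker genes allowed (0.13), with the nearer class (0.0240) and without HTO3 (0.0150, with -0.0714 as the other end of the range without 1 set). In adventitial-like cells the Wnt list median reversed with the stricter filter (0.0541), at 1500 UMIs (0.0544) and with the nearer class (0.000940), the chemokine list with doublets kept (0.0129) and without HTO1 (0.0158, with -0.18 as the other end of the range without 1 set), and the BMP list with doublets kept (-0.0164). The cause was not tested. Of the 15 genes named in the split, the alternatives other than leaving out a set named 0 to 6 again in alveolar-like and 1 to 9 in adventitial-like cells.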

Other observations

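The mesothelial-like and chondrocyte-like cells were set against the named fibroblasts together, a comparison chosen only after the result was seen, with no test. The genes named were likewise chosen after their values were seen. The 318 mesothelial-like cells had more complement and less fibroblast matrix transcript than the fibroblasts. Msln was found in 99.1% of them at 3000 UMIs, against 1.06% of adventitial-like cells. Cadherins and catenins had a median log2 ratio of 0.65, within the random lists (94.13th percentile), with Cdh3, the P-cadherin gene, at 33.5 against 0.0582 CPM (8.85) and Jup at 103 against 21.1 (2.29), while Cdh11 was lower (-0.44). Complement was higher (1.19, 99.87th percentile, 6 of 10 members higher and 2 lower in every hashtag set), with C3 at 8071 against 1802 CPM and Clu, the clusterin gene, at 1579 against 29.5, but C7 was lower (-5.70). The lipid and retinoid list was lower (median -1.69, 0.01st percentile, 4 of 13 higher and 8 lower), although Aldh1a2 stood at 764 against 50.2. The Wnt list was split (4 of 10 higher and 5 lower), with a median of -0.56 (0.99th percentile) and a mean of 0.025, and with Rspo1 at 683 against 20.1 and Sfrp2, a secreted Wnt modulator, at 734 against 2.24 among the higher members. Fibrillar collagens and small proteoglycans (median -1.38, 2 of 16 higher and 13 lower), basement membrane (-1.46, 4 of 15 and 11), elastic fibre (-1.41, 3 of 16 and 9), protease (-2.04, 3 of 14 and 10) and growth factor genes (-3.37, 1 of 13 and 10) were lower, the latter with Pdgfra, the gene of PDGF receptor alpha found on many fibroblasts, at 13.2 against 505. Col4a3 (2.96) and Col4a4 (4.08) were higher in them against this trend. Dissociation stress genes, a sign of handling, were also lower (-0.95, 0.02nd percentile, 0 of 15 higher and 12 lower), as were activated fibroblast (-4.04, 1 of 15 and 9), chemokine (-2.52, 2 of 12 and 7) and BMP genes (-0.69, 3 of 11 and 7).

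The 74 chondrocyte-like cells had 790 CPM of Cdh11 against 390 in the named fibroblasts (log2 ratio 1.02, 0.89 to 1.14). The activated fibroblast and TGF-beta response list was higher (median 1.48, above all random lists). With 0.5 counts added, 9 of 16 members counted as higher and 2 as lower in every hashtag set. Postn, the periostin gene, stood at 142 against 5.58 CPM, Runx2, a transcription factor of skeletal tissue, at 65.1 against 1.13, and Spp1, the osteopontin gene, at 1581 against 35.4. The Wnt list lay within the random lists (median -0.38, 3.85th percentile, mean 1.38), with 4 of 11 members higher and 2 lower in every set and a median below 0 in 3 of 5 sets. Wif1 stood at 747 against 1.40 and Rspo3, a Wnt amplifier, at 614 against 4.54. Fmod was higher (3.15) and so was Lum (3.31). Complement was lower (median -2.51, 1 of 10 higher and 8 lower), with C3 at 63.6 against 1802, and so were basement membrane (-1.06, 2 of 15 and 9), protease (-1.27, 1 of 14 and 9) and elastic fibre genes (-0.67, 4 of 16 and 8). The chemokine (-2.38, 1 of 13 higher and 4 lower) and growth factor medians (-0.38, 5 of 13 and 6) also lay below the random lists, each in 4 of 5 sets below 0. Dissociation stress genes had a median of -0.27 (1.27th percentile), with 2 of 15 higher and 7 lower in every set. Hashtag sets HTO2 and HTO3 held only 2 and 4 of these cells. With 0.5 counts added, a gene with 0 UMIs in so few cells counts as higher where its fibroblast level is low. The Wnt median was 1.69 in HTO2 and 0.87 in HTO3, and the chemokine median 1.15 in HTO2. The numbers of members and medians by set given for these cells thus depend in part on the added counts, and do not show that the sets agree.

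Among the alveolar-like cells, Spp1 had 1206 UMIs in 8 cells, and 3 cells of HTO5 brought its level there to 628 CPM; it was chosen after its values were seen. A small adventitial-like cluster of 85 cells was led by the interferon-response genes Ifit1, Ifit3, Rsad2 and Isg15 and had Cdh11 at 425 CPM. An unnamed cluster of 22 cells with mesothelial and epithelial markers was led by Sftpc and had Cdh11 at 520.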
